A study of Mus musculus with 7 samples.

How the data were processed

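RNA sequencing had been done on CD4 T cells sorted from tumours of an orthotopic hepatocellular carcinoma transplant model in mice. Per the labels' protocols, RNA was taken with TRIzol and libraries followed a standard Illumina procedure. The submitters' processing notes name CASAVA 1.8, HISAT2 2.0.5 and featureCounts 1.5.0-p3, without their roles or settings. The genome build, the annotation and the use of strand are not given in the sources used here, so no coordinates are printed, and counts of overlapping or antisense genes and of near-identical copies are uncertain. The values the authors deposited are raw counts per gene, 1 whole number per gene and library, in a table of 15588 genes (13268 protein-coding and 2320 non-coding) that also gives Entrez gene numbers and Gene Ontology terms. No entry lacked a gene name. Between 72.4% and 78.1% of the counts from 2 to 200 in a library were even numbers, where single fragments counted once would give about equal numbers of even and odd values; counts of 1 to 3 may therefore stand for fewer fragments than they show. The constant-region genes of the T cell receptor and of immunoglobulins were not analysed here.

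Each of the 7 columns was assigned to day 0 or day 7 by its name, and none to a single sample, because the columns' last digits do not follow the numbers in the sample titles. Total counts ranged from 21910818 to 28333855, and each library had a count for between 11698 and 12521 genes. The exact two-sided permutation p over 21 splits was 0.429 for total counts, 0.429 for genes detected, 0.714 for the share of the 10 largest genes (5.48% to 5.75%) and 0.714 for the share of the 13 mitochondrial genes (2.08% to 2.58%). With 2 against 5 libraries the smallest p such a test can give is 0.0476. Spearman's rho across genes lay between 0.913 and 0.934 for 11 pairs of libraries within a day and between 0.904 and 0.927 for 10 pairs between days. The chi-square statistic per degree of freedom was at least 74.2 for every pair, so no library was a copy of another within sampling noise.

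Genes were filtered with filterByExpr, scaled with TMM factors (0.988 to 1.01) and tested day 7 against day 0 with edgeR 4.0.16 (robust glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over 12929 genes and a threshold of 0.05. The common dispersion was 0.974. CPM of single genes use the TMM factors, and CPM sums of other-cell lists use total counts. Standard errors are the log2 change divided by the root of the F statistic. A count of 0 was read against a floor of 3 counts, which over the day 0 group is 0.0569 CPM. A gene with 1 to 3 day 0 counts was given as a ratio with an exact 95% binomial interval. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Fixed gene lists with at least 5 tested members (35 of 44) were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The call of the proliferation list alone held with an estimated correlation. The direction of the test differed from the sign of the median in the T helper 1 and 2, apoptosis, histone acetyltransferase and NK cell lists, none of which was called. The T cell core, activation and costimulation, TGF-beta signalling, apoptosis and other histone methyltransferase lists, also not called, had a negative median and a positive mean. The 15 lists of other cell types were summed as CPM and compared by an exact permutation test on log2(sum + 1).

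The tests, gene lists, naming rule and alternatives were fixed before the data were examined. The rule named the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with at least 20 CPM in the higher group and no overlap between groups (predicted genes and receptor segments left out), a panel of 16 T cell genes whatever their values, and up to 3 members in each direction of each list described. Not every gene the rule selected is described here. Other genes named in the text were chosen after their values were seen: Klrb1c, Klrc1, Zbtb16, Cd8a, Cd8b1, Lyz2, Alb, Hspa1a, Hspa1b, Ifit3, Ncr1, Tyrobp, Fcer1g, Il2rb, Cxcr6, Fasl, Mmp9, Ass1, Txndc5, Pecam1, Cd74, H2-Aa, H2-Eb1, H2-Ab1, Xcr1, Zbtb46, Peg13, Mlkl and Casp1, and Jund, Ldha, Pkm, Eno1 and Pgk1 as remaining called members of their lists. On simulated counts with the dispersions of these libraries and 200 changed genes of at least 20 CPM, 12259 genes were tested and the test recovered 76% of genes changed by a factor of 4 and 32% of those changed by a factor of 2, with 3 unchanged genes among 111 calls. The simulated counts were drawn independently for each library. In the real data, day 7 libraries 5 and 6 set against the rest gave 83 changed genes, so these rates may not hold there.

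Alternatives were RLE, upper-quartile or no scaling factors, no filter on low counts or a minimum mean of 5 CPM, DESeq2 1.42.0, limma-voom with and without sample weights, protein-coding genes without mitochondrial and immunoglobulin genes, glmTreat against a factor of 2, and each library left out in turn. In the last, a day with 1 library left is assumed to vary like the other day. Leaving out day 7 libraries 5 and 6 together was added after the data were seen, as was a camera test of 2029 Gene Ontology terms of 15 to 300 tested genes. A result not past its threshold in either setting was counted as unchanged whatever its sign. A block on the replicate numbers of the sample titles was planned and not run, because the columns could not be matched to the titles. A block on the columns' last digits was added after the data were seen.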

Results

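Gene expression was measured by RNA sequencing in CD4 T cells, the helper lineage of T lymphocytes, sorted from tumours in a mouse model in which hepatocellular carcinoma is transplanted into the liver. Samples were labelled as taken on day 0 (2 libraries) or day 7 (5 libraries) after the model was set up. The labels do not say what tissue stood for tumour on day 0. The series title places the work in a study of epigenetic control of CD4 T cell immunity in this cancer. The deposited table held 15588 genes, of which 13268 were protein-coding. Total gene counts were 24351820 and 28333855 for the day 0 libraries and from 21910818 to 26955367 for the day 7 libraries. Libraries are named here by the last digit of their column in that table (day 0 libraries 2 and 3, and day 7 libraries 1, 2, 3, 5 and 6), because these digits do not follow the numbers in the sample titles. Levels are given in CPM, the counts scaled to a common library size, as mean ± SD over 2 day 0 and 5 day 7 libraries. Log2 changes are day 7 against day 0 ± standard error. Nothing states that the libraries came from separate animals, so p-values measure only the spread between these libraries.

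By day 7 the sorted CD4 T cells carried more transcripts of cell division and of 7 of 19 glycolysis genes. They also carried more of the activation receptors Tnfrsf4 and Tnfrsf9, 2 of 20 tested members of a list that was not called and whose test pointed lower. They carried fewer transcripts of the immediate early genes Dusp1, Btg2, Junb and Jund, 4 of the 18 tested members of their list, and of Klrk1 and Cd160, receptor genes that natural killer (NK) cells also express. Of the gene lists called, the proliferation list alone kept its call with an estimated correlation between genes (adjusted p = 0.268 for glycolysis and 0.266 for early response and heat shock). Mki67 rose from 178 ± 33.0 to 656 ± 143 CPM, Tpi1 from 82.0 ± 17.1 to 197 ± 36.4 CPM and Tnfrsf9 from 11.4 ± 2.17 to 64.5 ± 8.33 CPM. Dusp1 fell from 944 ± 212 to 299.7 ± 54.3 CPM and Klrk1 from 389 ± 50.5 to 187 ± 24.8 CPM. Cd3e, a subunit of the T cell receptor complex, stood at 567 ± 111 and 529 ± 35.6 CPM. Of 12929 genes tested with edgeR's quasi-likelihood test, 199 changed at a Benjamini-Hochberg adjusted p below 0.05, 138 higher and 61 lower at day 7. These 199 genes did not overlap between the groups in CPM, as was the case for 15.3% of all tested genes against 9.52% by chance.

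Among the fixed lists, that of cell cycle genes had the most members called. All 38 tested members of the proliferation list had a positive log2 change, with a median of 1.72. Over all genes tested 26 rose, or 36 when adjusted over the list alone (camera adjusted p = 2.78e-36, and adjusted p = 0.0225 with an estimated correlation). Top2a (Entrez 21973), the topoisomerase that untangles replicated DNA, rose from 118 ± 19.5 to 471 ± 88.0 CPM (edgeR adjusted p = 4.24e-07). Rrm2 (Entrez 20135), a subunit of ribonucleotide reductase, rose from 28.1 ± 10.1 to 139.8 ± 16.8 CPM, and Ccna2 (Entrez 12428), which encodes cyclin A2, from 26.8 ± 12.5 to 131 ± 26.4 CPM. The proliferation marker Mki67 (Entrez 17345) had a log2 change of 1.88 ± 0.20 (edgeR adjusted p = 6.96e-05). Aurkb (Entrez 20877), a mitotic kinase, rose from 2.60 ± 0.263 to 37.7 ± 4.08 CPM, a call lost with limma-voom. The mean list level, as log2(CPM + 1) over the members, was 4.75 and 4.85 in the day 0 libraries and lay between 6.34 and 6.64 in the day 7 libraries. Sgo2a (Entrez 68549), which protects centromeric cohesin, had 2 counts in all over the day 0 libraries and 40.2 ± 13.6 CPM at day 7, a count ratio of 1044 with a 95% counting interval from 289 to 8622. The number of proliferation genes called was 12 with limma-voom and 15 with limma-voom and sample weights.

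**Figure D1:**
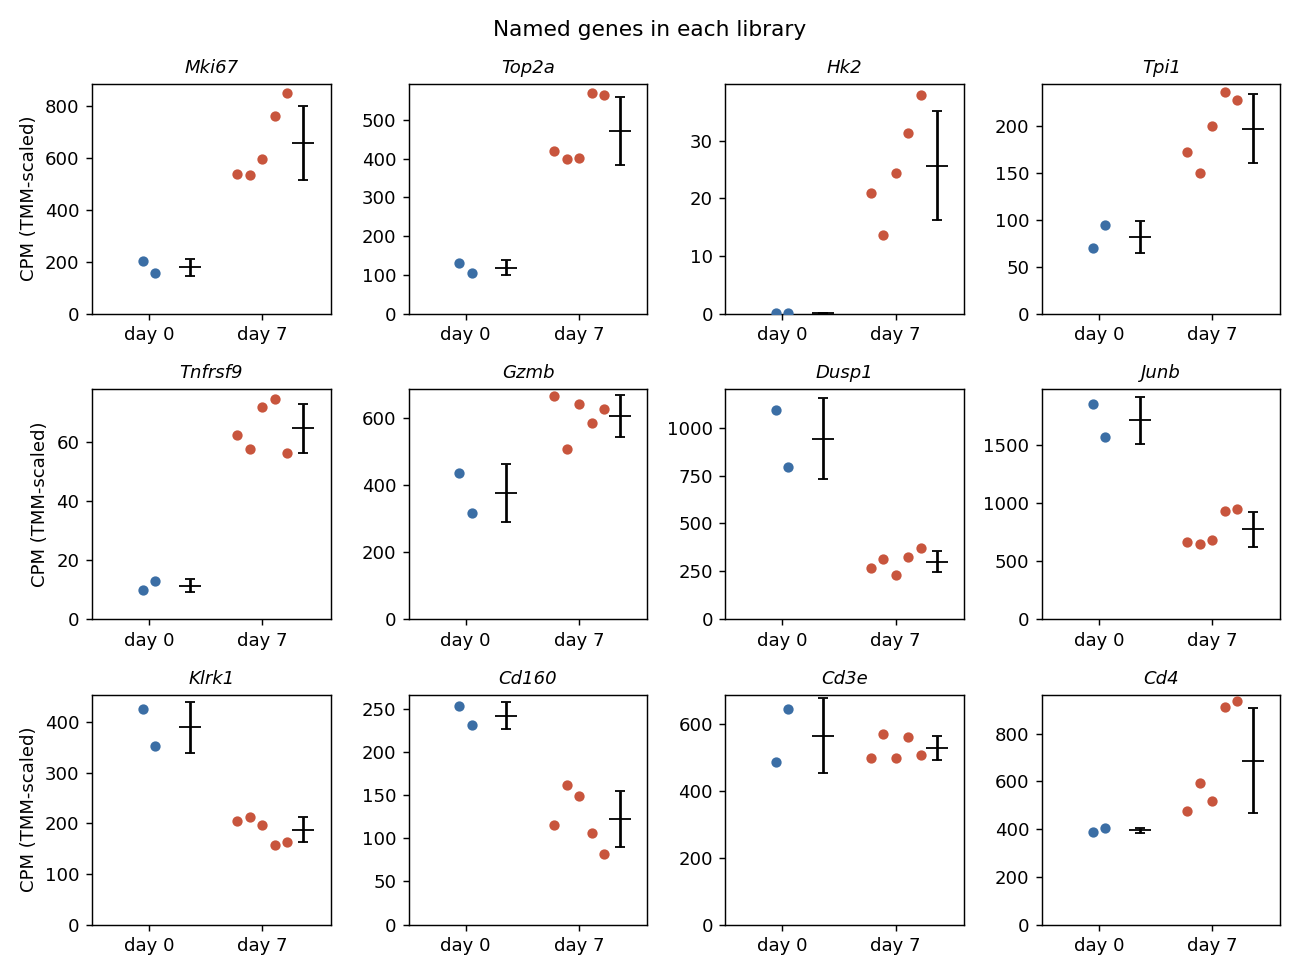
CPM of 12 named genes on the vertical axes, with 1 point per library in blue for day 0 (2 libraries) and red for day 7 (5 libraries), and a black dash with bars for the mean and SD of each group. Mki67, Top2a, Hk2, Tpi1, Tnfrsf9 and Gzmb were higher in every day 7 library, Dusp1, Junb, Klrk1 and Cd160 were lower, and Cd3e overlapped (567 ± 111 against 529 ± 35.6 CPM).

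Members of the glycolysis list rose in part. Of 19 tested members 7 rose, or 8 adjusted over the list alone, and none fell (camera adjusted p = 9.69e-06, and adjusted p = 0.268 with an estimated correlation). Tpi1 (Entrez 21991), the triosephosphate isomerase, had a log2 change of 1.26 ± 0.22 (edgeR adjusted p = 0.00137), and Ldha, Pkm, Eno1 and Pgk1 had log2 changes of 0.76, 0.53, 0.51 and 0.61. Hk2 (Entrez 15277), the inducible hexokinase, went from 0.0922 ± 0.0716 to 25.7 ± 9.41 CPM (edgeR adjusted p = 1.44e-05), a change that rests on 5 counts at day 0. Slc16a3 (Entrez 80879), a lactate exporter, had 2 counts at day 0 and 25.4 ± 18.6 CPM at day 7, a ratio of 649.5 with a 95% counting interval from 179.6 to 5366. Hk2 stood at 0.0416 and 0.143 CPM in day 0 libraries 2 and 3, and both day 0 counts of Slc16a3 were in day 0 library 3. The calls of Hk2 and Slc16a3 were lost with limma-voom (adjusted p of 0.225 and 0.456). The oxidative phosphorylation list was called higher with a median log2 change of 0.16 (camera adjusted p = 0.0419, and adjusted p = 0.268 with an estimated correlation). Of its 57 members 0 passed edgeR's gene test over all genes or over the list alone, 2 were higher at an unadjusted p under 0.05, and DESeq2 called 2 higher. The call of the list was lost without any 1 of 4 libraries (day 0 library 3 and day 7 libraries 1, 2 and 3, adjusted p from 0.0508 to 0.131). The hypoxia list was not called (median log2 change 0.02, camera adjusted p = 0.482). Without day 0 library 2 the number of glycolysis genes called was 4, as it was with limma-voom.

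Among receptors and transcription factors of activated and regulatory T cells, 3 of 22 tested members of the regulatory T cell list rose (7 adjusted over the list alone, where 1 fell). The list was called higher with a median log2 change of 1.33 (camera adjusted p = 2.88e-05, and adjusted p = 0.0703 with an estimated correlation). Tnfrsf9 (Entrez 21942), which encodes the costimulatory receptor 4-1BB, had a log2 change of 2.51 ± 0.37 (edgeR adjusted p = 2.27e-04). Tnfrsf4 (Entrez 22163), which encodes OX40, rose from 1.54 ± 1.88 to 33.7 ± 9.73 CPM (log2 change 4.46 ± 0.80). Its log2 change was 7.27 without day 0 library 2 and 3.56 without day 0 library 3. The call of Tnfrsf4 was lost with limma-voom. Both receptors are also induced on activated conventional T cells. Ikzf2 (Entrez 22779), which encodes the transcription factor Helios, rose with a log2 change of 0.87 ± 0.21. This call was lost without any 1 of 4 libraries (day 0 library 2 and day 7 libraries 1, 2 and 5, adjusted p from 0.0621 to 0.505). Foxp3, the lineage factor of regulatory T cells, did not pass at 71.1 ± 24.8 CPM on day 7 (log2 change 1.24 ± 0.34, edgeR adjusted p = 0.0736, and 0.0295 without day 7 library 6). Il2ra was at 190.7 ± 43.8 and 199.7 ± 52.4 CPM. The activation and costimulation list was not called, and its test pointed lower (camera adjusted p = 0.147). It had 2 members higher over all genes, and 2 higher and 2 lower adjusted over the list alone. The list was called lower without day 7 library 6 (camera adjusted p = 0.0424) and without day 7 libraries 5 and 6 (camera adjusted p = 0.00153).

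Among inhibitory receptor genes, Lag3, Pdcd1, Ctla4 and Havcr2 differed widely between day 7 libraries. Lag3 (Entrez 16768) had 1 count at day 0 and 29.9 ± 29.2 CPM at day 7, a count ratio of 1548 with a 95% counting interval from 278 to 61176. Its call (edgeR adjusted p = 0.0458) was lost without any 1 of 3 libraries (day 0 libraries 2 and 3 and day 7 library 3, adjusted p from 0.0549 to 0.541). The day 0 count was in day 0 library 2. At day 7 it stood at 3.99, 10.8, 11.4, 61.1 and 62.4 CPM in libraries 1, 2, 3, 5 and 6. Pdcd1, which encodes PD-1, was at 7.17 ± 4.20 CPM at day 0 and 83.4 ± 78.2 CPM at day 7 (edgeR adjusted p = 0.572). Ctla4 stood at 38.1 ± 12.9 and 210.4 ± 118 CPM (adjusted p = 0.284). It stood at 47.3 and 29.0 CPM in the day 0 libraries and at 128, 113 and 132 CPM in day 7 libraries 1, 2 and 3. Without day 7 libraries 5 and 6, an alternative chosen after the data were seen, Ctla4 was called higher (log2 change 1.69, edgeR adjusted p = 0.00245). There Lag3, Pdcd1 and Havcr2 were not called (edgeR adjusted p of 0.1755, 0.323 and 0.998). Havcr2 was at 2.87 ± 4.06 and 36.1 ± 44.0 CPM (adjusted p = 0.818) and Tox at 38.6 ± 2.36 and 89.4 ± 35.3 CPM (adjusted p = 0.0610). DESeq2 called Pdcd1, Ctla4 and Tox higher. Of 20 tested members of the inhibitory receptor and exhaustion list 1 rose and 1, Cd160, fell, or 3 and 1 adjusted over the list alone. The list was not called (camera adjusted p = 0.482). Beside these values, the summed CPM of the CD8 T cell genes Cd8a and Cd8b1 was 204 and 177 in day 7 libraries 5 and 6 and between 2.29 and 18.3 in the other libraries.

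A few immediate early genes fell by day 7. Of 18 tested members of the early response and heat shock list 17 had a negative log2 change, with a median of -0.96. Over all genes tested 4 fell, or 7 adjusted over the list alone (camera adjusted p = 1.64e-23, and adjusted p = 0.266 with an estimated correlation). The 4 were Dusp1 (Entrez 19252), a phosphatase of MAP kinases, Btg2 (Entrez 12227), an antiproliferative early gene, and the AP-1 genes Junb (Entrez 16477) and Jund. Dusp1 had a log2 change of -1.65 ± 0.16 (edgeR adjusted p = 3.88e-06), Btg2 went from 720 ± 100 to 296 ± 45.1 CPM, and Junb from 1707 ± 205 to 772 ± 151 CPM. The mean list level was 8.56 and 8.17 in the day 0 libraries, 6.67, 6.86 and 6.85 in day 7 libraries 1, 2 and 3, and 7.97 and 8.12 in day 7 libraries 5 and 6. Without day 7 libraries 5 and 6, an alternative chosen after the data were seen, 16 members of the list fell. No heat shock member passed over all genes. Hspa1a and Hspa1b stood higher in day 7 libraries 5 and 6 (448.5 and 494 CPM, and 775 and 974 CPM) than in both day 0 libraries (239.9 and 299 CPM, and 667 and 666 CPM). They are near-identical copies whose counts cannot be separated with certainty.

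The steepest falls under the naming rule also included the small Maf genes Maff (Entrez 17133, from 62.5 ± 42.8 to 12.1 ± 4.35 CPM) and Mafk (Entrez 17135, from 143 ± 42.2 to 47.9 ± 10.9 CPM). Dnajb9 (Entrez 27362), a chaperone of the endoplasmic reticulum, fell from 177 ± 37.6 to 52.9 ± 14.3 CPM. Rhob (Entrez 11852) fell from 236 ± 8.97 to 64.2 ± 21.4 CPM (log2 change -1.88 ± 0.24, edgeR adjusted p = 3.96e-05). Otud1 (Entrez 71198), a deubiquitinase gene, fell from 77.7 ± 20.8 to 24.0 ± 3.93 CPM. Zbtb10 (Entrez 229055) had a log2 change of -1.92 ± 0.47 and Dguok (Entrez 27369) of -1.53 ± 0.39. Several of these calls depended on single libraries, while the log2 change of Rhob stayed between -2.08 and -1.78 with any 1 library left out. Maff (log2 change -1.41 in place of -2.37, adjusted p = 0.657) and Mafk (adjusted p = 0.106) were not called without day 0 library 2, nor Otud1 without day 0 library 3 (adjusted p = 0.278). Zbtb10 lost its call without any 1 of 5 libraries (day 0 libraries 2 and 3 and day 7 libraries 3, 5 and 6, adjusted p from 0.0592 to 0.149) and Dguok without any 1 of 6 (each library except day 0 library 3, adjusted p from 0.0572 to 0.549). Among the 8 steepest rises, Cpd (Entrez 12874, a carboxypeptidase) went from 0.158 ± 0.0713 CPM, or 8 counts, to 27.9 ± 11.2 CPM. Snx9 (Entrez 66616, a sorting nexin) had a log2 change of 4.81 ± 1.09, with 1.41 and 0.0357 CPM in day 0 libraries 2 and 3. Its log2 change was 8.97 without day 0 library 2 and 3.85 without day 0 library 3. The call of Snx9 was lost without any 1 of 3 libraries (day 7 libraries 1, 3 and 5, adjusted p from 0.0555 to 0.126).

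The tissue residency list was called lower, with 10 of 13 members at a negative log2 change, and a median of -0.42 (camera adjusted p = 1.99e-05, and adjusted p = 0.266 with an estimated correlation). Of these members 0 passed edgeR's test over all genes, 5 were lower adjusted over the list alone, 6 were lower at an unadjusted p under 0.05, and DESeq2 called 1 lower. The mean list level was 7.25 and 7.04 in the day 0 libraries, 6.47, 6.61 and 6.52 in day 7 libraries 1, 2 and 3, and 7.02 and 6.97 in day 7 libraries 5 and 6. The cytotoxic effector list moved both ways and was not called (camera adjusted p = 0.886), with 1 member higher and 1 lower over all genes, and 5 higher and 3 lower adjusted over the list alone. Gzmb (Entrez 14939), which encodes granzyme B, rose from 376 ± 85.3 to 604 ± 61.8 CPM (log2 change 0.69 ± 0.14, edgeR adjusted p = 0.00994, and 0.339 without day 0 library 3). Klrk1 (Entrez 27007), which encodes the activating receptor NKG2D, fell by 1.06 ± 0.16 on the log2 scale (edgeR adjusted p = 2.56e-04). Cd160 (Entrez 54215) fell from 242 ± 15.8 to 123 ± 32.5 CPM. Its call was lost without day 0 library 2 or day 7 library 5 (adjusted p of 0.0968 and 0.0579). Tbx21, which encodes the Th1 factor T-bet, fell from 309 ± 34.3 to 203 ± 22.4 CPM (log2 change -0.60 ± 0.16, edgeR adjusted p = 0.0491). This call was lost without any 1 of 6 libraries (each except day 7 library 6, adjusted p from 0.0702 to 0.515), and with RLE scaling or library sizes alone. Tbx21 was the single member of the Th1 list past the test over all genes or adjusted over the list alone. With all libraries the list was not called (camera adjusted p = 0.482). Ifng stood at 409 ± 104 CPM at day 0 and 196 ± 68.4 CPM at day 7 and did not pass (edgeR adjusted p = 0.276). Without day 7 libraries 5 and 6, an alternative chosen after the data were seen, Ifng was called lower (log2 change -1.46, edgeR adjusted p = 3.69e-04).

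The naive and central memory list was not called (camera adjusted p = 0.590). Ccr7 stood at 71.4 ± 25.7 and 85.4 ± 44.5 CPM and Tcf7 at 622 ± 100 and 768 ± 97.2 CPM. The T cell core list had a median log2 change of -0.03, with no member past the test over all genes and 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.828). Cd4 itself was at 395 ± 11.2 CPM at day 0 and 687 ± 221 CPM at day 7 (edgeR adjusted p = 0.450). The Th2, Th17, follicular helper and chemokine receptor lists had no member past the test over all genes and were not called (camera adjusted p of 0.915, 0.765, 0.765 and 0.765). Adjusted over the list alone they had 1 member higher, none, 1 lower and 1 lower. The apoptosis list was not called (camera adjusted p = 0.590). The TGF-beta signalling list had no member past the test over all genes or adjusted over the list alone (camera adjusted p = 0.428).

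Interferon-stimulated genes were split within day 7. All 25 tested members of the type I interferon response list had a positive log2 change, with a median of 0.75. Of these 2 rose, or 4 adjusted over the list alone (camera adjusted p = 9.69e-06, and adjusted p = 0.572 with an estimated correlation). Ifih1 (Entrez 71586), a sensor of viral RNA, rose from 25.6 ± 7.68 to 70.5 ± 10.2 CPM. Its call was lost without day 0 library 2 or day 7 library 2 (adjusted p of 0.281 and 0.0555). Ifi27l2a (Entrez 76933) rose to 177.5 ± 54.9 CPM (log2 change 1.24 ± 0.28). That call was lost without any 1 of 3 libraries (day 0 library 3 and day 7 libraries 2 and 3, adjusted p from 0.0776 to 0.182). The mean list level was at most 5.13 in the day 0 libraries, 6.12, 6.19 and 6.05 in day 7 libraries 1, 2 and 3, and 5.16 and 4.98 in day 7 libraries 5 and 6. The interferon gamma response list was not called, with no member past the test over all genes and 1 higher adjusted over the list alone (camera adjusted p = 0.0622, and 0.0163 and 0.00516 without day 7 library 5 or 6).

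**Figure D2:**
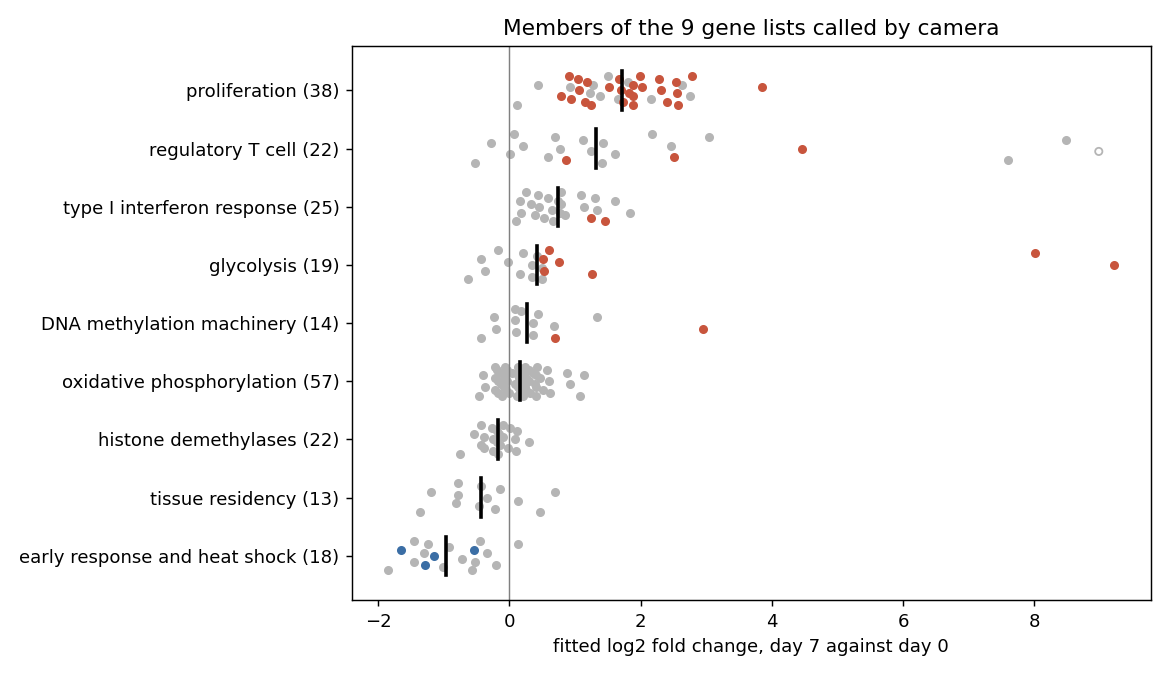
Fitted log2 fold changes of day 7 against day 0 for the tested members of the 9 gene lists called by camera, 1 point per gene, red where the gene rose, blue where it fell, grey where it did not pass the gene test, and open where day 0 had no count; black bars are list medians and the tested members are given in brackets. The proliferation list had 26 of 38 members past the test, and the oxidative phosphorylation, tissue residency and histone demethylase lists had none.

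Chromatin regulators moved little as groups. The DNA methylation machinery list was called higher (median log2 change 0.27, camera adjusted p = 0.0315, and adjusted p = 0.287 with an estimated correlation). Of its 14 members 2 were higher, also when adjusted over the list alone. These were Uhrf1 (Entrez 18140), from 12.4 ± 6.93 to 95.5 ± 16.2 CPM (edgeR adjusted p = 2.20e-05), and Dnmt1 (Entrez 13433), from 177 ± 2.31 to 286.5 ± 40.3 CPM, the pair that copies DNA methylation during replication. The log2 change of Uhrf1 was 2.95, and 3.68 without day 0 library 2. The Dnmt1 call was lost without any 1 of 4 libraries (day 0 libraries 2 and 3 and day 7 libraries 2 and 5, adjusted p from 0.0702 to 0.182), and that of the list without any 1 of 3 (day 0 libraries 2 and 3 and day 7 library 2, adjusted p from 0.0650 to 0.1997). The histone demethylase list was called lower (median log2 change -0.17, camera adjusted p = 0.0288, and adjusted p = 0.268 with an estimated correlation). Of its 22 members 0 passed edgeR's test over all genes or over the list alone, 1 was lower at an unadjusted p under 0.05, and DESeq2 called 0. The call of this list was also lost without any 1 of 3 libraries (day 0 libraries 2 and 3 and day 7 library 3, adjusted p from 0.0557 to 0.185). In the Polycomb list Aebp2 alone rose, from 200.2 ± 12.8 to 306 ± 20.2 CPM, with the call lost without any 1 of 5 libraries (day 0 libraries 2 and 3 and day 7 libraries 1, 3 and 5, adjusted p from 0.0668 to 0.402). The list had 2 members higher adjusted over the list alone and was not called (camera adjusted p = 0.0780, and 0.0424 without day 7 library 6). Ezh2, the Polycomb histone methyltransferase, was at 78.1 ± 13.3 and 137 ± 27.8 CPM. It was called by DESeq2 and did not pass with edgeR (log2 change 0.82 ± 0.24, adjusted p = 0.0981, and 0.0475 without day 7 library 2). The lists of other histone methyltransferases, histone acetyltransferases, histone deacetylases, protein arginine methyltransferases and SWI/SNF remodelling were not called (camera adjusted p of 0.722, 0.886, 0.401, 0.578 and 0.482), with no member past the test over all genes and 1 histone methyltransferase higher adjusted over the list alone. With fry, which asks whether a list's genes move one way on balance, SWI/SNF remodelling was called higher (adjusted p = 0.0194).

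Genes listed as markers of other cells were also detected. The summed CPM of the NK cell list, at day 0 mostly Klrb1c, was 865 ± 78.2 at day 0 and 473 ± 119 at day 7. Its member Klre1 fell from 109 ± 8.02 to 55.6 ± 8.55 CPM (edgeR adjusted p = 0.0495), a call lost without any 1 of the 7 libraries (adjusted p from 0.0585 to 0.444). The macrophage and monocyte sum was 15.1 ± 7.36 at day 0 and 93.4 ± 102 at day 7, with 251 and 140.4 in day 7 libraries 5 and 6 and at most 32.4 in the others. Csf1r, the macrophage growth factor receptor, had no count at day 0 and 14.8 ± 16.5 CPM at day 7, with 0.148 CPM in day 7 library 1 and 41.6 CPM in day 7 library 5. Its call (edgeR adjusted p = 0.0491) was lost without any 1 of 6 libraries (each except day 7 library 1, adjusted p from 0.0571 to 0.511). The dendritic cell sum was 24.3 ± 12.2 and 151 ± 118, the neutrophil sum 228 ± 33.3 and 144 ± 28.8 and the hepatocyte sum 101 ± 17.5 and 156 ± 35.4. At day 0 Mmp9 made up 227 CPM of the neutrophil sum and Ass1 75.5 CPM of the hepatocyte sum, so these sums do not measure those cell types as such. In the dendritic cell sum at day 7, Cd74 made up 57.9 CPM, and H2-Aa, H2-Eb1 and H2-Ab1 made up 27.5, 20.6 and 18.0 CPM. Of its 8 tested members 6 had a positive log2 change, while Xcr1 and Zbtb46 had a negative one. This sum does not measure dendritic cells as such either. The B cell sum was 15.7 ± 11.5 and 32.7 ± 13.4 and the CD8 T cell sum 2.95 ± 0.933 and 85.3 ± 96.3. The plasma cell sum was 67.0 ± 34.6 and 71.5 ± 17.0, the endothelial sum 93.0 ± 25.8 and 126 ± 32.6, the hepatoma and biliary sum 25.6 ± 0.512 and 17.1 ± 11.5, and the stellate cell and fibroblast sum 11.6 ± 5.09 and 15.1 ± 2.98. Of these, Txndc5 made up 54.2 CPM of the plasma cell sum and Pecam1 83.3 CPM of the endothelial sum at day 0. The gamma-delta T cell, mast cell and basophil, erythroid and platelet sums reached at most 11.2 CPM in any library. The exact two-sided permutation test over 21 splits gave its smallest possible p, 0.0476, for the dendritic cell and neutrophil sums and 0.0952 for the CD8 T cell, NK cell and B cell sums. The adjusted p over the 15 sums was 0.286 for these 5 and higher for the others. As lists tested by camera none of the other-cell lists was called, with adjusted p of 0.0780 for dendritic cells and 0.119 for hepatocytes (0.0424 without day 7 library 6).

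**Figure D3:**
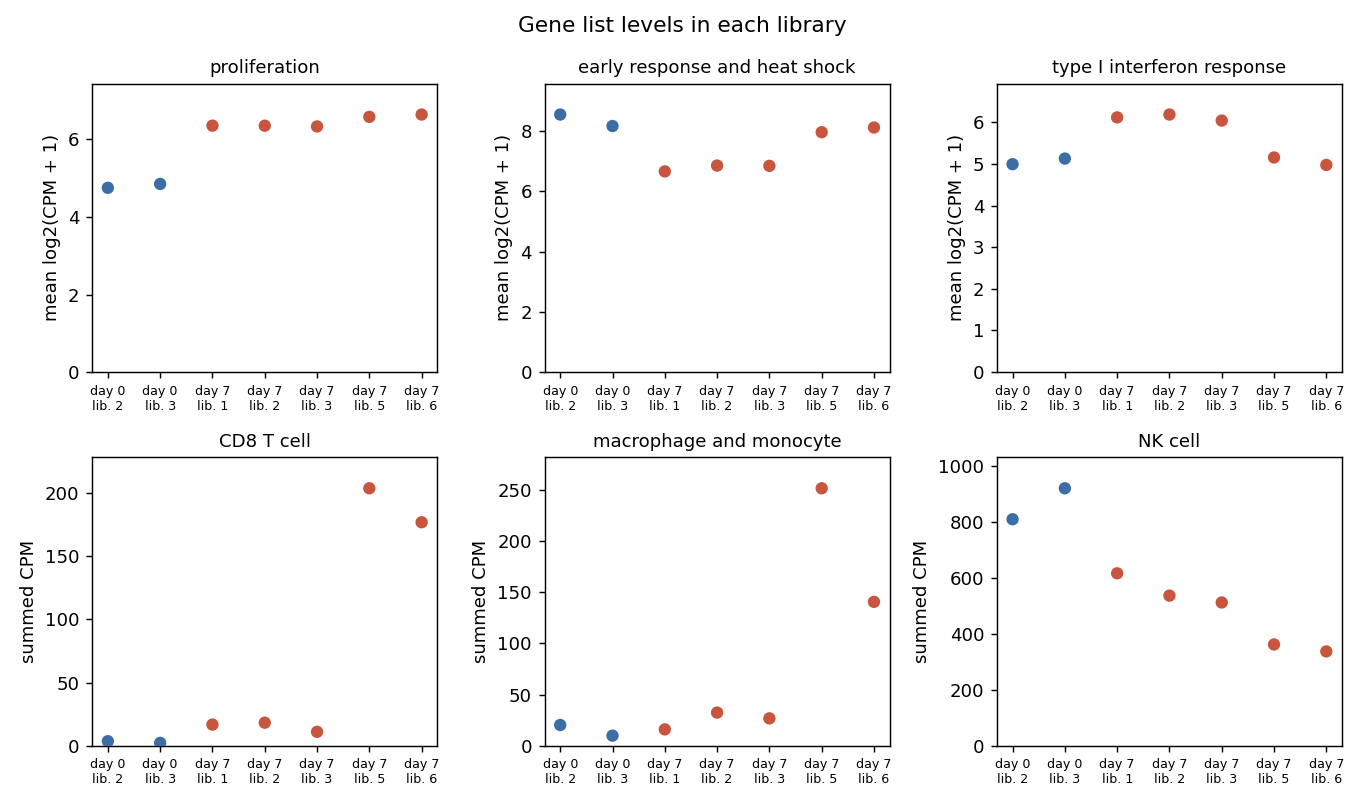
Level of 6 gene lists in each library (horizontal axes), as mean log2(CPM + 1) over the tested members in the upper row and as summed CPM in the lower row, with day 0 in blue and day 7 in red. The proliferation level was higher in every day 7 library (6.34 to 6.64 against 4.75 and 4.85), while day 7 libraries 5 and 6 stood apart from libraries 1, 2 and 3 in the other lists shown.

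The split of the 199 calls between higher and lower genes depended on the test. limma-voom called 53 genes higher and 94 lower, and DESeq2 638 higher and 192 lower. Without day 7 library 5 the count was 127 (87 higher and 40 lower), and the count of lower genes was 30 without day 0 library 2 and 38 without day 0 library 3.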

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

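The tests of the 3 patterns weighed below were chosen after the results were seen, except the 2 counts over splits of the libraries and the comparison with random lists.

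Among 70 values compared between the 5 day 7 libraries, 2 had 1 library far from the others, fewer than the 1 in 20 that chance gives. The rule looks for 1 library apart from the rest. Day 7 libraries 5 and 6 stood apart together in several markers and so mask each other. The count therefore does not show that the day 7 libraries were alike. The summed CPM of the B cell list was 56.0 in day 7 library 3 and 31.1 in the nearest library (gap over range 0.756, critical value 0.71). The platelet sum was 0.0456 CPM in day 7 library 6 and 0 in the other day 7 libraries (gap over range 1), below the floor of 3 counts.

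The first pattern was the rise of proliferation genes. The real split of the 7 libraries was the 1 among 21 that changed 199 genes, against at most 83 in another split. It was also the 1 that called 26 proliferation genes higher, against 0 in the others. For both counts the permutation p over splits was 0.0476, the smallest that 21 splits can give, so chance is made less likely and is not excluded. The split with 83 genes set day 7 libraries 5 and 6 against the rest, which points to a structure among the day 7 libraries. The tables argue against cells of another type in those libraries as the whole cause, since 21 of the 26 members were still called without them, and against a shift of all genes at this expression level, since 0 of 10000 random lists matched on mean CPM reached the list's median of 1.72 (highest 0.251). More cycling CD4 T cells at day 7 was not tested directly, since no cell was measured singly. A day 0 sample from another tissue or handled at another time, which the labels do not describe, stays open and untested.

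The second pattern was the lower median of the early response and heat shock list at day 7, of which 4 of 18 members were called. Dilution of T cell RNA by other cells would lower T cell genes as well, but the T cell core genes had a median log2 change of -0.0284 (quartiles -0.18 and 0.25) where the list had -0.96. Handling that varied between libraries within a day remains a candidate explanation, because for 9 of the 18 members a day 7 library reached the lower day 0 library. For each of these 9 members, library 5 or 6 did so. The count therefore cannot tell handling from cells of another type in those libraries, which was not tested for this list. Hspa1b, for example, stood at 667 and 666 CPM on day 0, at 179, 175 and 156 in day 7 libraries 1, 2 and 3, and at 775 and 974 in libraries 5 and 6. For the 4 members that were called, Dusp1, Btg2, Junb and Jund, no day 7 library reached day 0, which the calls themselves all but require, so a difference between the days and handling that differed by day both stay open.

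The third pattern was the fall of Klrk1, Klrc1, Klre1, Cd160 and Zbtb16, whose product PLZF directs innate-like T cells such as NKT cells. NK cells in the day 0 libraries are argued against by the low day 0 level of Ncr1, Tyrobp and Fcer1g. Their summed CPM averaged 17.9 at day 0 (12.5 and 23.3), while Klrb1c stood at 632 and 714 CPM in the day 0 libraries. The higher day 7 mean of their sum, 42.1 CPM, is not counted as evidence, because myeloid cells also express Tyrobp and Fcer1g. The macrophage and monocyte sum was also higher at day 7 (93.4 ± 102 against 15.1 ± 7.36 CPM). A CD4 sort is meant to remove NK cells, but Cd8a was still detected, so the sort itself is not counted as evidence here. Cd8a stood at 132.5 and 90.9 CPM in day 7 libraries 5 and 6, and at 3.37 and 0.178 CPM in the day 0 libraries. Cells of another type in day 7 libraries 5 and 6 are argued against as the whole cause, since the median log2 change of the 5 genes was -0.98 with and -0.93 without these libraries, and 4 of the 5 were still called. A larger share of innate-like T cells at day 0 remains a candidate explanation. Of 13 other genes of such cells, 9 had a negative log2 change, with a median of -0.42 (camera p = 0.0124 with an estimated correlation, not adjusted). These 13 genes are not one of the 44 lists fixed before the data were examined. They were tested in the same libraries, so they give no independent support. With edgeR 0 of the 13 passed the gene test, 5 were lower and 2 higher at an unadjusted p under 0.05, and DESeq2 called 1 higher and 1 lower. Without day 7 libraries 5 and 6, Klrb1c was called lower (log2 change -0.87). Conventional T cells also express several of these genes, such as Il2rb, Cxcr6 and Fasl, and lower expression in the same cells was not tested.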

How the results depend on the processing

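The alternatives without day 7 libraries 5 and 6 and with a block on the columns' last digits were chosen after the data were seen. Scaling by RLE, upper-quartile or no factors, the filter at 5 CPM and the restriction to protein-coding genes left each count of genes and lists within 1.5 times its value. Under the alternatives run, no named gene or list called in either setting changed direction, but limma-voom turned the balance of calls from more genes higher to more genes lower. Without a filter 375 genes changed (249 higher and 126 lower), 82 list members passed and 8 early response genes fell. DESeq2 changed 830 genes (638 higher and 192 lower; 198 of the 199 among them) with 116 list members. limma-voom called 53 higher and 94 lower, with 33 list members, 12 proliferation and 4 glycolysis genes, and with sample weights 67 higher and 114 lower, with 15 proliferation and 4 glycolysis genes. Against a factor of 2, glmTreat called 27 genes (26 higher and 1 lower), with 13 list members, 7 proliferation genes, 2 glycolysis genes and 1 early response gene, by its stricter hypothesis. An estimated correlation called 1 list, higher, and 0 lower, and fry 3, all higher, against 9 (6 higher and 3 lower). The fry calls were proliferation, regulatory T cell and, gained, SWI/SNF remodelling. Without day 7 libraries 5 and 6, 107 genes were lower (118 higher), 16 early response genes fell and 15 lists were called (10 higher and 5 lower). The lists gained were naive and central memory, interferon gamma response, Polycomb and hepatocyte, called higher, and Th1 and activation and costimulation, called lower. Leaving out 1 library gave 127 to 189 changed genes, 87 to 153 higher, 30 to 59 lower, 37 to 57 list members, 19 to 25 proliferation genes, 4 to 6 glycolysis genes, 3 to 6 early response genes and 6 to 13 lists (4 to 9 higher and 2 to 4 lower). Of the 50 genes the naming rule selected, 14 calls were lost with limma-voom, among them Hk2 (log2 change 7.89), Sgo2a (9.36), Slc16a3 (8.65), Lag3 (9.02) and Cpd (7.19), whose day 0 levels rest on at most 8 counts, and Tnfrsf4 (5.35), Snx9 (6.13) and Aurkb (3.84), with 75, 35 and 136 day 0 counts. The others were Tbx21, Ikzf2, Ifih1, Aebp2, Dnmt1 and Csf1r. With glmTreat 25 calls were lost. Without day 7 libraries 5 and 6, 9 calls were lost and 3 gained, namely Ifng (log2 change -1.46, adjusted p = 3.69e-04), Ctla4 (1.69, adjusted p = 0.00245) and Foxp3 (1.40, adjusted p = 0.0494). Over all alternatives the adjusted p ranged from 8.38e-07 to 1 for Ifng and from 0.00245 to 1 for Ctla4 and from 0.00243 to 1 for Foxp3. These ranges take in glmTreat, which tests for a change beyond a factor of 2, so their upper ends do not measure the choice of processing alone. The causes of the differences between alternatives were not tested. The list test already uses voom values, so limma-voom adds no separate list result, and glmTreat has none. The planned block on the titles' numbers was not run, because columns could not be matched to titles. Whether the columns' own digits pair samples is unknown: digits 2 and 3 occur on both days, and the deviations from the day means of same-numbered libraries had correlations across genes of -0.0049 and -0.0013. With this digit as a replicate block, 82 genes changed (40 higher and 42 lower), of which 50 were among the 199, with 8 proliferation, 3 glycolysis and 13 early response genes called. Digits 1, 5 and 6 occur on day 7 only, so the day effect in that fit rests on libraries 2 and 3 of each day. Its differences from the main fit therefore cannot be read as an effect of pairing alone. In that fit 19 of the 50 genes lost their call and 2 gained one, and 3 lists gained and 1 lost a call.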

Other observations

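The Gene Ontology test and the genes named here were chosen after the data were seen. Of 2029 Gene Ontology terms, 35 were higher and 3 lower at day 7 by camera, and 0 were called with an estimated correlation. Most of the higher terms concerned replication and mitosis, led by DNA replication initiation (22 genes, 6 higher, median log2 change 0.95, camera adjusted p = 1.89e-07). The term for negative regulation of viral genome replication had 2 of 44 genes higher (camera adjusted p = 0.00271). The lower terms were positive regulation of NK cell mediated cytotoxicity (5 of 29 genes lower and 1 higher, camera adjusted p = 0.0203), response to endoplasmic reticulum stress (1 of 69 lower, camera adjusted p = 0.0228) and negative regulation of the MAPK cascade (2 of 34 lower, camera adjusted p = 0.0259).

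Among single genes in none of the fixed lists, Casp1, which encodes the inflammasome caspase, rose from 8.90 ± 8.35 to 43.7 ± 13.3 CPM (edgeR adjusted p = 0.0312). Mlkl, the effector of necroptosis, had no count at day 0 and lay between 9.70 and 21.3 CPM in the day 7 libraries (edgeR adjusted p = 3.60e-04). Peg13, an imprinted non-coding gene, fell from 142.5 ± 18.4 to 40.8 ± 7.33 CPM (edgeR adjusted p = 1.49e-04). Zeros were common in all libraries: 51 genes had no count in both day 0 libraries and a count in the 5 day 7 libraries, against 14 to 52 for the other pairs of libraries set against the remaining 5.

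Day 7 libraries 5 and 6 differed from day 7 libraries 1, 2 and 3 in several markers, given here as values only. Cd8a stood at 132.5 and 90.9 CPM in libraries 5 and 6 and at 5.77, 12.1 and 8.24 CPM in libraries 1, 2 and 3, and Lyz2 at 147 and 67.5 against 0.0370, 6.64 and 6.66 CPM. Cd4 stood at 913 and 936 against 475, 591 and 519 CPM, and Pdcd1 at 149.7 and 184 against 43.2, 6.12 and 34.3 CPM. Ifit3, an interferon-stimulated gene, stood at 18.9 and 18.8 against 151, 112 and 94.7 CPM, and Alb, the hepatocyte albumin gene, at 0.761 and 0 against 33.6, 23.3 and 28.4 CPM. The labels name no batch that separates these libraries.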
